A study of Bacillus subtilis PY79 with 8 samples.

How the data were processed

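The data were 8 anti-ParB ChIP-seq libraries of Bacillus subtilis PY79, 1 per genotype. Per the labels' protocols, cells were grown in CH medium at 37 °C and fixed with 3% formaldehyde for 30 min. Per the same protocols, 6 libraries were prepared for the NextSeq550 and the 2 ECE libraries for the NextSeq500. Each deposited file gives a raw coverage signal, a whole number for each position of a chromosome of 4.03 Mb, and the file headers name only position and value. The deposited values were not scaled between libraries, as their totals differ. The coverage of opt KCK with R80 has digit-group separators in its larger values and was read after removing them. The aligner, its settings, the treatment of reads that match several places and the genome build are not given in the sources used here. A whole-library control without immunoprecipitation was not used here.

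Depth was estimated from the coverage itself. Differences of coverage between neighbouring bases were negatively correlated at a lag of 42 bp in all 8 libraries, so each read was taken to cover 42 bp and the number of reads as total coverage divided by 42. Estimated reads ranged from 604285 to 7412626, and median coverage was 6, 6, 7, 7, 6, 4, 11 and 33 for untagged, KCK, opt KCK and ECE, with R80 before R80A. The share of coverage near the summits has 95% binomial intervals from these read numbers, such as 71.3% to 71.4% for untagged Spo0J with R80 and 27.9% to 28.1% for opt KCK with R80A. They cover counting error only, and would be too narrow if reads are mates of pairs or copies of a molecule. Median coverage is a small whole number, so scaling by it is coarse. Scaling by the median of 1 kb bins was added as an alternative.

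Coverage was divided by the genome median of its library. The fixed rule took maxima of the mean over the 8 libraries, smoothed over 1 kb and above 3 times the genome median, merged within 20 kb. It gave 11 maxima. After the data were examined, a second list was made of narrow summits, with a mean of at least 10 times the median and a 500 bp signal at least 3 times that found 1 to 3 kb away, as a geometric mean over the libraries. The contrast was first set lower and then raised to 3 because the lower setting took in shoulders of neighbouring summits. This list has 9 summits, of which 6 have no other within 20 kb. Because both lists use the R80 libraries, a summit needs signal there to be listed.

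Signal at a site is the mean within 0.5 kb, and flank signal the mean from 1 to 10 kb on both sides. Spreading share and width were taken from the mean profile of isolated sites, each divided by the median coverage 20 to 40 kb away, leaving out 10 kb around other sites. R80A was tested against R80 with an exact two-sided sign-flip permutation test over the 4 construct pairs, which has 16 sign patterns and a smallest p of 0.13. Comparisons of 2 libraries carry no test and are set beside 10000 lists of random windows drawn from 3382 background windows. Bins of 1 kb were tested with limma 3.58.1 in R 4.3.3 on log2 of the scaled signal plus 0.05, with construct and allele in the model, a mean-variance trend and Benjamini-Hochberg adjustment. Bins with a mean under 0.1 were to be left out, and there were 0. The fit had 3 residual degrees of freedom and 51.4 prior ones, which come from all bins. Positions were handled with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

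The bin test was tested on simulated data with 200 of 4033 bins changed, and recovered 50 of 50 at each of 2-fold, 4-fold, 8-fold and 16-fold, with 17 false calls. The simulated noise was independent between bins, and no difference in scaling or background gradient between alleles was put in. It therefore does not show how reliable the calls on the real bins are. On simulated profiles at 6 sites, the spreading share came out at 0.666% where 0.674% was put in, and at 70.6% for a broad profile made with 70.6%. The named regions were to be all sites, and the 5 regions over 20 kb from a site with the largest change in each direction. Genes were also to be named. The gene table at hand belongs to another assembly of the strain, so it was used only to count rRNA genes, and gene lists, genes changed by R80A, named genes, native spo0J, soj and pelB, the parS motif and the control motif of the related protein Noc were not analysed here. Alternatives fixed beforehand were other scalings, windows, distance limits, pseudocounts, bin sizes and filters, robust moderation, a fit without blocks, free permutation and leaving out each construct.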

Results

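Spo0J is the ParB protein of Bacillus subtilis, a DNA-binding protein that loads at parS sites near the replication origin and spreads along the neighbouring DNA. Chromatin immunoprecipitation with antibodies against ParB, followed by sequencing, was carried out on 8 strains of the laboratory strain PY79 grown in rich medium at 37 °C and fixed with 3% formaldehyde. Per the labels, each strain lacked native spo0J and carried a copy at pelB from which the parS site had been removed. The copy was untagged, or carried 1 of 3 modifications labelled KCK, opt KCK and ECE, each with arginine (R80) or alanine (R80A) at residue 80. The labels do not say what KCK and ECE stand for. There was 1 library for each of the 8 genotypes, so values of a single library have no replicate error, and the 4 construct pairs were the only unit for testing R80A. Constructs are not replicates of a genotype. The 4 R80 libraries held an estimated 2294738 (untagged), 2732858 (KCK), 3964537 (opt KCK) and 7412626 (ECE) reads. The R80A libraries held 764985, 866569, 604285 and 3875407 in the same order. Median coverage per base ranged from 4 to 33. Positions are those of the deposited files, which cover a single chromosome of 4.03 Mb, and the genome build is not given in the sources used here. Angles are degrees clockwise from position 1.

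The signal was concentrated in a few narrow summits, most of them close to position 1. There were 9 such summits, at positions 3729401 (332.9°), 3965301 (353.9°), 3970626 (354.4°), 3984676 (355.6°), 4023551 (359.1°), 47676 (4.3°), 185301 (16.5°), 471626 (42.1°) and 1020451 (91.1°). The highest was at 359.1°, where coverage within 0.5 kb averaged 1531 ± 238 times the genome median over the 4 R80 libraries (SD, n = 4 constructs). The lowest was the summit at 91.1°, with 34.5 ± 22.6. Untagged Spo0J had a median of 283 over the 9 summits, KCK 292, opt KCK 687 and ECE 565. The rule for narrow summits was chosen after the data were seen. The rule fixed beforehand, which takes any region above 3 times the genome median, gave 11 maxima, of which 5 lay in regions holding these summits and 6 in regions holding none. Over those 11 maxima the library medians ranged from 4.85 to 8.86, since most of the list is then made of low regions. Matching to the parS sequence and to genes was not analysed here, so the summits are not called parS sites.

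R80A was compared with R80 in each construct to see how much of the signal depends on residue 80. With R80A, coverage relative to the genome median was lower at all 9 summits in all 4 constructs. Averaged over constructs, the flanks lost more than the summit at 8 of the 9, with the ECE pair at 42.1° as an exception (-3.99 against -4.31). At 91.1° the mean log2 ratio was -2.54 in the flanks and -3.15 at the summit. The R80A flanks there were at 0.982 to 1.05 times the genome median, so their ratio is a lower bound of the loss and does not show which lost more. For each construct the median log2 ratio of R80A to R80 over the 9 summits was taken. These medians averaged -2.79 ± 0.85 (SD, n = 4 construct pairs), a 6.91-fold difference. In the flanks, 1 to 10 kb away, the medians averaged -4.62 ± 0.64, a 24.6-fold difference. R80A flanks at 4.3°, 16.5°, 42.1°, 332.9° and 355.6° were at only 1.40 to 3.22 times the genome median and hold background as well, so this too is a lower bound of the loss. The share of all coverage lying within 10 kb of the summits, a span of 3.95% of the chromosome, averaged 76.7% ± 5.94 with R80 and 20.6% ± 5.5 with R80A. The exact two-sided sign-flip permutation test gave p = 0.13 for each of these 3 measures. This is the smallest value that 4 pairs allow, so this test cannot reach the usual threshold here, whatever the size of the difference.

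The summits kept between 1.87 and 447 times the genome median in the R80A libraries. At 359.1° the R80A libraries averaged 300 ± 119 and at 4.3° 70.8 ± 52.5, while the flanks of those summits averaged 3.67 and 2.19. By construct the median log2 ratio at the summits was -2.21 for untagged Spo0J, -2.47 for KCK, -2.43 for opt KCK and -4.05 for ECE. In the flanks it was -4.16, -4.29, -4.46 and -5.57. The summits at 353.9° and 354.4° lie within 10 kb of each other, so the flanks of each hold the other summit. The untagged flank median is the value at 353.9° and that of opt KCK the value at 354.4°. Both ECE libraries were prepared for another instrument model than the other 6, and without them the averages were -2.37 ± 0.14 and -4.31 ± 0.15 (SD, n = 3 construct pairs, exact sign-flip p = 0.25, the smallest possible). Over the 11 maxima fixed beforehand the ratio was -0.63 ± 0.44 at the maxima and -0.73 ± 0.26 in the flanks, both with an exact p of 0.13 over n = 4 pairs. At the maxima, the median of each construct fell in a region without a narrow summit, at 45.7° for opt KCK and 345.2° for the others. It therefore does not describe the summits. With the mean over maxima in place of the median, the ratios at the maxima and in the flanks were -1.47 and -1.92. With the median and division by the origin-to-terminus trend they were -0.23 and -0.20. For those 11 maxima, scaling by mean coverage turned the direction, to 1.34 and 1.24. For the 9 summits the average of the medians kept its direction under that scaling, with -0.81 and -2.65. Division by the trend gave -2.20 and -3.89 there. Single summits did not all keep it under scaling by mean coverage. At 355.6° untagged Spo0J had 192 times the genome median with R80 and 71.7 with R80A. The 2 libraries have equal median coverage, but mean coverage was 3.0 times higher with R80, so R80A lies above R80 there.

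**Figure D1:**
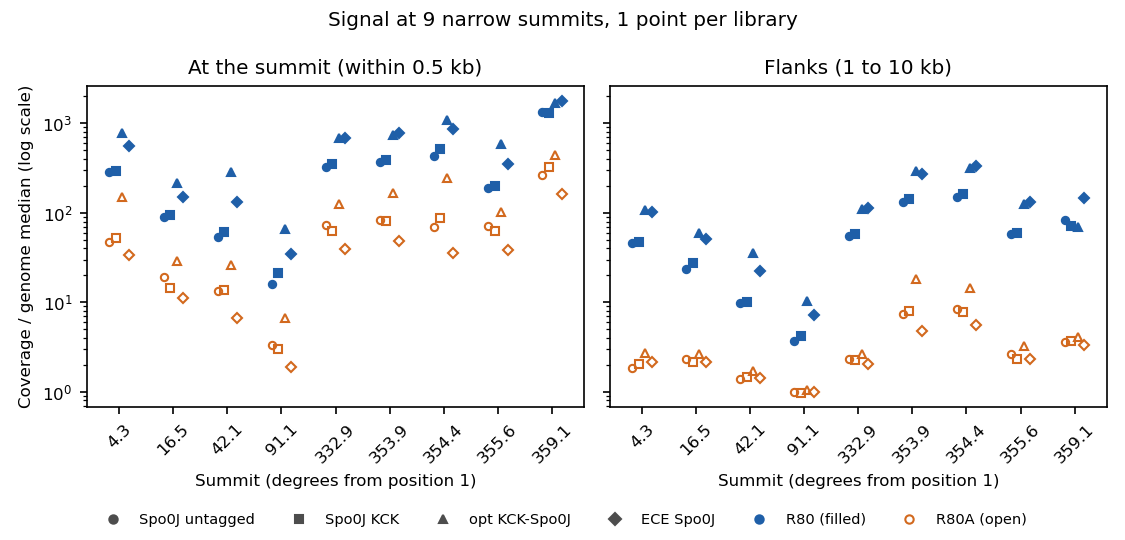
Coverage divided by the genome median (log scale) at each of the 9 narrow summits, within 0.5 kb (left) and 1 to 10 kb away (right), with 1 point per library and the marker giving the construct. At every summit and flank each R80A library (open) lies below the R80 library (filled) of its construct.

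Spreading was described by how much of the signal lay away from the site, independent of its height. With R80, coverage extended several kb from the summits, and with R80A it was mostly held within 1 kb. Over the 11 maxima, 57.2% ± 2.24 of the coverage above background within 10 kb lay more than 1 kb from the site with R80, against 27.4% ± 3.91 with R80A (SD, n = 4 constructs each). Over the 6 isolated narrow summits the shares were 57.9% ± 1.88 and 14.3% ± 2.56. The rule for narrow summits asks for low signal 1 to 3 kb away over all libraries, those with R80A among them. It therefore favours sites with a low share, which the rule for the 11 maxima does not. The distance at which the mean profile fell under 10% of its centre was 4.13 ± 0.25 kb with R80 at these 6 summits and 0.5 kb in all 4 R80A libraries, the shortest distance the measure can give. Over the 11 maxima it was 4 ± 0.41 kb against 0.75 ± 0.29 kb.

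The share was lower with R80A in 4 of 4 pairs by either list, with differences of -29.8 ± 3.11 percentage points (11 maxima) and -43.6 ± 1.26 (6 summits). The exact sign-flip permutation test gave p = 0.13 for the share and the width by either list (n = 4 pairs, two-sided). Without the ECE pair the differences were -29.7 ± 3.80 and -43.7 ± 1.54 (n = 3 pairs, exact p = 0.25). The distance to 50% of the centre differed less, at 0.75 ± 0.29 kb against 0.5 kb (exact p = 0.5, n = 4 pairs).

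**Figure D2:**
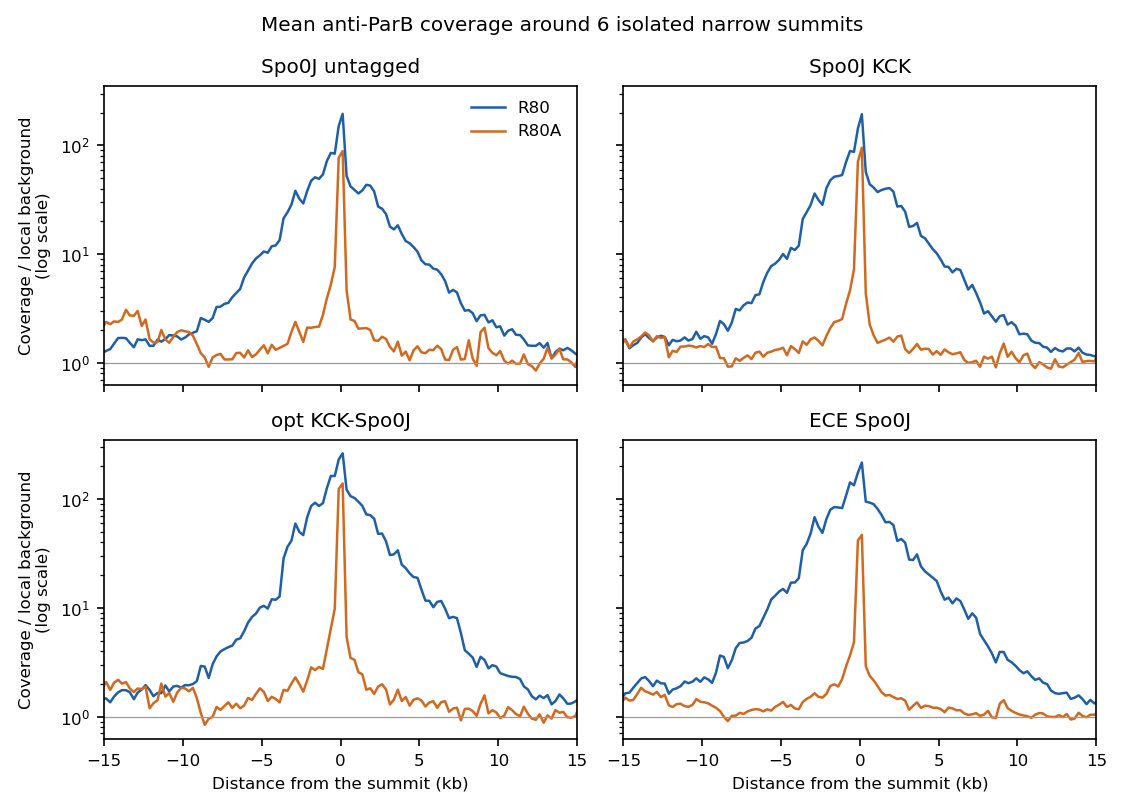
Mean coverage divided by local background (log scale) against distance from the summit in kb, averaged over the 6 isolated narrow summits, for R80 (blue) and R80A (orange) in each of the 4 constructs. The R80 profiles decline over about 10 kb on both sides, and the R80A profiles leave a narrow central peak.

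**Figure D3:**
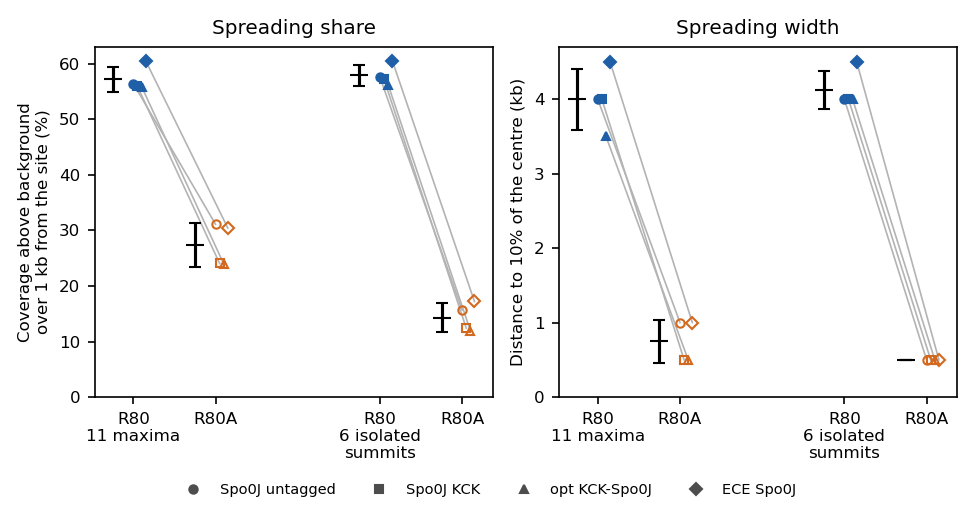
Share of coverage above background lying over 1 kb from the site (left, in %) and distance to 10% of the centre (right, in kb), for each library and for the 11 maxima and the 6 isolated summits. Lines join the libraries of a construct, and bars give the mean and SD of the 4 constructs. With R80A every library has a share of 31.1% or less and a width of 1 kb or less.

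The modified proteins were compared with untagged Spo0J within each allele, the comparison closest to the series title, which concerns checking labelled DNA-binding proteins. KCK differed little from untagged Spo0J at the 9 summits, with 1.06-fold the signal in the R80 background and 0.967-fold in the R80A background. opt KCK was higher at 9 of 9 summits in both backgrounds, by 2.55-fold with R80 and 1.96-fold with R80A. ECE was higher at 9 of 9 summits with R80 (2.0-fold) and lower at 9 of 9 with R80A (0.556-fold). In the R80 flanks the ratios were 1.04-fold for KCK, 2.22-fold for opt KCK and 2.15-fold for ECE. In the R80A flanks they were 0.989, 1.21 and 0.913. Under scaling by mean coverage the summit log2 ratios with R80 fell from 1.35 to 0.56 for opt KCK and from 1.0 to 0.18 for ECE, and the flank ratios to 0.36 and 0.28. With R80A the summit ratios were then 0.73 and -0.73.

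The opt KCK and ECE values at the summits lay outside the range spanned by 95% of 10000 lists of as many random background windows, in both backgrounds, and those of KCK lay inside. In the flanks the opt KCK and ECE values lay outside it with R80 and inside it with R80A. The random windows were 1 kb long, while a flank is a mean from 1 to 10 kb on both sides. Lying inside the range therefore does not show that flanks were alike. With R80A, the opt KCK flanks were above those of untagged Spo0J at 9 of 9 summits. Those of ECE were above at 3 and below at 6. The random lists describe the libraries compared and are no test between genotypes. Over the 11 maxima the R80 ratios of opt KCK and ECE were 0.40 and 0.68 on the log2 scale, and scaling by mean coverage turned them to -0.38 and -0.13. Only the ECE libraries were prepared for the other instrument model, so ECE and instrument cannot be told apart. opt KCK also differed from the rest in its resistance marker. In the labels KCK is written before spo0J for opt KCK and after it for the KCK construct, so these are not called the same modification.

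The difference between R80A and R80 was set against that of untagged Spo0J to see whether it was of similar size in the modified constructs. At the 9 summits the log2 ratio differed from that of untagged Spo0J by -0.26 for KCK, -0.23 for opt KCK and -1.84 for ECE. In the flanks the values were -0.13, -0.30 and -1.41. Under scaling by mean coverage the ECE values were -0.90 and -0.47, and those of opt KCK turned to 0.32 and 0.24. After division by the origin-to-terminus trend the ECE values were -1.64 and -1.48, and those of opt KCK -0.21 and -0.91. The share of coverage beyond 1 kb of the 6 isolated summits differed by -2.87, -2.38 and -1.46 percentage points, and over the 11 maxima by -6.54, -6.61 and -4.80. With 1 library per genotype none of these could be tested. Over the 11 maxima the values at the maxima were -0.62, -0.64 and -1.06. The medians behind them fell in regions without a narrow summit, so they do not describe the summits.

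Across the chromosome, the bins lower with R80A surrounded the summits and the origin, and those higher lay mostly on the opposite side unless the trend was divided out. Of 4033 bins of 1 kb, 1680 passed an adjusted p of 0.05 in limma with construct as a block, 885 lower and 795 higher with R80A. Within 10 kb of a narrow summit 156 of 159 bins passed, all lower, with a median log2 ratio of -3.57 over those bins. Of the 795 higher bins, 781 lay on the side of the chromosome opposite position 1. Changes of at least 2-fold were found in 231 lower and 2 higher bins. After division by a smooth origin-to-terminus trend 265 bins were lower and 46 higher, of which 24 lay on the side of position 1 and 22 opposite, so the placement of the higher bins was lost. After scaling by mean coverage 114 were lower and 3861 higher. Leaving out the ECE pair gave 440 higher bins, leaving out opt KCK 536, KCK 594 and untagged 807. Neighbouring bins are not independent.

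Among regions more than 20 kb from a summit, the lower ones with the largest change were 3450001 to 3519000, 101001 to 123000, 3530001 to 3570000, 418001 to 428000 and 513001 to 550000. Their extreme bins had log2 ratios from -0.94 ± 0.13 (SE) to -0.59 ± 0.13, lower in 4 of 4 pairs. None of these 5 bins passed after the trend was divided out. Other lower bins did, such as that from 2231001 (log2 ratio over the trend -0.95, limma adjusted p = 7.3e-06). Of all bins more than 20 kb from a summit, 46 lower and 45 higher ones passed after the trend. The 5 higher regions with the largest change were 2237001 to 2290000, 1626001 to 1746000, 1883001 to 1907000, 2054001 to 2081000 and 1156001 to 1177000. Their extreme bins had log2 ratios from 0.90 ± 0.15 to 1.09 ± 0.13, and these 5 bins also passed after the trend, with limma adjusted p from 4.1e-04 to 0.0322. The bin in the region from 1156001 was higher in all but 1 of the 4 pairs, the others in 4 of 4. It lies in a 5 kb window raised over the trend in KCK (2.45) and ECE (2.11) with R80A and at 0.938 to 1.14 in the other 6 libraries, so this call rests mostly on 2 libraries.

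Few bins passed in the comparison of constructs when both alleles were pooled. The fit gives each construct the same difference in both alleles, so a difference that varies between alleles goes into the residual. At the summits, opt KCK was above untagged Spo0J at 9 of 9 in both backgrounds, by 2.55-fold with R80 and 1.96-fold with R80A. ECE was above it at 9 of 9 with R80 and below it at 9 of 9 with R80A. The low counts therefore do not show that the constructs were alike near the summits. In limma, 0 bins passed for KCK, 2 for opt KCK and 1 for ECE, against 179, 410 and 152 at an unadjusted p under 0.05. The bin from 4024001 to 4025000, 0.95 kb from the summit at 359.1°, was higher in opt KCK by a log2 ratio of 2.70 ± 0.54 (SE, limma adjusted p = 0.0115) and in ECE by 3.06 ± 0.54 (limma adjusted p = 0.00194). After the trend was divided out, and in the fit without blocks, 0 bins passed for opt KCK and ECE. The bin overlaps a coverage gap, found after the data were seen. In untagged Spo0J and KCK with R80 the gap ran from 4023865 or 4023866 to 4024941, about 1077 bp. In opt KCK and ECE it ended at 4024078 or 4024079, a length of 212 and 215 bp. With R80A, the stretch from 4024179 to 4024841 had 2.69 times the genome median in untagged Spo0J, 0.684 in KCK, 6.93 in opt KCK and 6.06 in ECE. Within the part of the gap shared by all constructs, untagged Spo0J with R80A had 2.93 and the 3 other R80A libraries 0.396 to 0.677. With R80 it was 0.378 in untagged Spo0J, 0.635 in KCK, 1.34 in opt KCK and 0.206 in ECE. Whether the gap is the deletion of spo0J given in the labels, and whether all strains carry the same one, was not analysed here, so the bin from 4024001 is not read as a difference in binding. Whether the untagged R80A strain lacks the deletion, or its library is mixed with another, was not analysed here either. The untagged R80A library is the reference of every R80A ratio to untagged Spo0J and of every difference from the R80A effect of untagged Spo0J, and these values depend on it. It also belongs to 1 of the 4 pairs behind each average of R80A against R80. Without that pair the 11 maxima gave -0.83 at the maxima, -0.81 in the flanks and -31.3 percentage points for the share. Averages over the narrow summits were not taken without it. The other opt KCK bin, 2233001 to 2234000, was higher by 0.98 ± 0.18 (limma adjusted p = 0.00455).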

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

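One difference between groups stood out by direction and was not tested, since each genotype has 1 library. ECE Spo0J was above untagged Spo0J at 9 of 9 narrow summits with R80 (median log2 ratio 1.0, range 0.41 to 1.28) and below it at 9 of 9 with R80A (median -0.85, range -1.01 to -0.47). The difference between these effects was -1.84 log2 units, and -0.90 under scaling by mean coverage. The order of the ECE and untagged libraries in the R80A background was the same under scaling by mean coverage (-0.73) and by the origin-to-terminus trend (-0.95). With R80, the ECE value was 0.18 under scaling by mean coverage. The untagged R80A library, 1 of the 4 behind the difference, also had the highest coverage of the 8 in the part of a coverage gap shared by all constructs, beside the summit at 359.1° (2.93 times the genome median).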

How the results depend on the processing

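Tests on narrow summits and with scaling by the median of 1 kb bins were chosen after the data were seen, the test by splits of the libraries was written down after its result was seen, and the other alternatives were fixed before the data were examined. No sign-flip test could pass the threshold in this design, so a test that stayed on its side of the threshold says nothing about stability. The cause of the shifts below was not tested. Mean coverage itself holds the summit signal, with 76.7% of coverage within 10 kb of the narrow summits with R80 and 20.6% with R80A. Compared with the median, scaling by it therefore lowers the R80 libraries more. "Pooled" values are medians over 8 libraries (enrichment), 6 comparisons (tag) or 3 constructs (tag by allele) at the 11 maxima, where they were 6.54, 0.07 log2 and -0.64 log2.

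Scaling by mean coverage gave pooled values of 2.73, -0.32 and -0.12. It reversed R80A against R80 to 1.34 at the maxima and 1.24 in the flanks, opt KCK against untagged with R80 to -0.38 and -0.51, ECE against untagged with R80 to -0.13 and -0.21, and the ECE tag by allele value in the flanks to 0.36. The opt KCK value in the flanks went from -0.07 to 0.47. Scaling by the origin-to-terminus trend gave 5.21, -0.13 and -1.36, and R80A against R80 became -0.23 at the maxima (exact p = 0.5) and -0.20 in the flanks. The mean over maxima in place of the median gave -1.47 and -1.92. A 250 bp window gave 7.28 for enrichment and -1.02 for tag by allele, and a 1 kb window 4.55 for enrichment. The narrow summits gave 205, 0.53 and -0.26, with the trend 97.9, 0.41 and -0.21, and with mean coverage 71.5 for enrichment and -0.19 for tag by allele, where the opt KCK value reversed to 0.32 (0.24 in the flanks) and the ECE value went from -1.84 to -0.90 (-1.41 to -0.47 in the flanks). Free permutation of the alleles gave an exact p of 0.286 at the maxima. Leaving out a construct gave -0.83 to -0.47 at the maxima, -31.3 to -29.1 percentage points for the share and -3333 to -3167 bp for the width. The mean differences in share and width kept their direction in every alternative run, from -44.3 to -14.9 percentage points and from -6500 to -250 bp. The value of -250 bp is the distance to 50% of the centre, which was lower in 2 of 4 pairs and equal in untagged and KCK. The value of -6500 bp is over all 9 narrow summits, of which 3 have another within 20 kb.

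Bins changed by R80A numbered 1680, and 3975 with mean coverage, 311 with the trend, 543 of the larger bins of 5 kb and 233 at 2-fold or more. Leaving out a construct gave 1146 to 1649 bins, with 440 (without ECE) to 807 higher ones against 795. Of the 8 splits of the libraries that part all 4 construct pairs, 1, the real one, gave as many as 1680 bins and the highest other 0, and 8 splits are too few for a share under 0.05. The other splits of the libraries leave pairs together. Every split but the real one puts part of the allele difference into the residual, so low counts in them were to be expected. For the tags, mean coverage gave 5 bins for opt KCK and 2 for ECE, and the trend and the fit without blocks each gave 0 for both. A pseudocount of 0.5 gave 1 for KCK, 9 for opt KCK and 2 for ECE, robust moderation 1 for KCK and 17 for opt KCK, bins of 500 bp 5 for opt KCK, bins of 5 kb 1, 10 and 2, and the median of 1 kb bins 1 for opt KCK. Exact and 2-mismatch motif matches, all alternatives of the Noc motif control and all those of the gene results were not run. Low median coverage limits the background values, most in opt KCK with R80A at 4.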

Other observations

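All tests in this part were chosen after the patterns were seen. With R80, the signal was not symmetric around 4 of the 6 isolated summits and dropped in steps. At 4.3° the profile reached 2.5 kb to the left and 6.25 ± 0.5 kb to the right (SD, n = 4 constructs), at 42.1° 2.5 kb and 5.5 ± 1.08 kb, and at 91.1° 1.75 ± 0.65 kb and 7.5 ± 0.71 kb. At 359.1°, where a coverage gap lies to the right, it reached 4 ± 1.23 kb to the left and 1.25 ± 0.96 kb to the right. It was nearly symmetric at 16.5° (8 and 7.5 kb) and 332.9° (4 and 3.75 ± 0.29 kb). At position 45476, left of the summit at 4.3°, coverage in neighbouring 500 bp changed 7.57-fold with R80 and 2.12-fold with R80A. The corresponding steps were 5.22-fold against 1.23-fold at 469326 and 6.07-fold against 1.29-fold at 3725601. These are the 3 largest of 12 steps, 1 per side of the 6 isolated summits, each placed where the mean R80 profile changed most, so the size with R80 and with R80A is not compared by a test. The position was the same in the 4 R80 libraries to the 50 bp grid of the search at 7 of the 12, and differed by 150 to 10200 bp at the other 5. The steps to the right of 4.3° and 359.1° were 1.99-fold against 1.81-fold and 2.17-fold against 2.04-fold.

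Background coverage more than 25 kb from any summit fell from position 1 to the opposite side in all 8 libraries, and more steeply with R80. Within 250 kb of position 1 it was 5.75-fold the terminus level with R80 and 2.88-fold with R80A, a log2 difference of -1.0 ± 0.17 (SD, n = 4 pairs, exact p = 0.13). Signal spreading continuously from the summits is argued against as the whole cause by bins over 200 kb from any summit and within 1 Mb of position 1, where the difference relative to the terminus was -0.51 ± 0.14 and lower in 4 of 4 pairs. Relative to the genome median, and with all positions pooled, the log2 ratio of R80A to R80 was -1.12 at 10 to 20 kb from a summit, -0.40 at 80 to 120 kb, -0.052 ± 0.064 at 120 to 200 kb and -0.071 ± 0.107 at 200 to 300 kb, so spreading as a part stays open. Unequal coverage stays open too. The pairs with equal median coverage, untagged and KCK, had a mean difference of -0.86, but the median is a whole number of 6 or 7, and mean coverage was 3.0 and 3.15 times higher with R80. A steeper copy number gradient in the R80 cells cannot be told apart from an immunoprecipitated background without input DNA, and the log2 difference changed by 0.59 per Mb.

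Outside the summits, 7 plateaus of 5 to 15 kb, at 9001 to 15000, 30001 to 35000, 90001 to 101000, 161001 to 176000, 598001 to 604000, 909001 to 916000 and 2990001 to 2997000, stood above the background. Those from 598001, 909001 and 2990001 overlap regions of the 11 maxima that hold no narrow summit, at 53.4°, 81.7° and 267.4°. The 7 plateaus were chosen by a mean over the R80A libraries above 2 times the trend, more than 5 kb from a summit. Regions that lose signal with R80A could hardly enter such a list. A plateau 2.05 kb from a summit, with a log2 ratio of -4.16, was left out. The ratio therefore cannot decide whether regions outside the summits hold signal of the kind seen there. For the plateaus listed, the R80A to R80 log2 ratio averaged 0.064 ± 0.65 (SD, n = 4 constructs). It went both ways, with 0.92 for untagged Spo0J, 0.04 for KCK, -0.05 for opt KCK and -0.65 for ECE, while the flanks of the summits had -4.16 to -5.57. The SD of the log2 level over the plateaus was 0.028 to 0.142 in the 8 libraries and that of their flanks 0.376 to 1.21. KCK with R80 ranged from 3.57 to 4.86 times the genome median and opt KCK with R80A from 4.75 to 5. The SD over plateaus was 0.126 of that of the flanks in the median library. Reads divided among near-identical copies may therefore give the plateaus their similar levels. Why those levels lie above the flanks was not tested, and the SD cannot decide it. In the R80A libraries the plateaus were at 3.61 to 7 times the genome median and their flanks at 0.75 to 2, while with R80 the ranges overlapped. As a candidate source of such copies, rRNA operons have 30 rRNA genes in 9 runs in the gene table. That table is of another assembly of the strain and was not placed on these positions.

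In 3 windows of 5 kb in the terminus region, opt KCK was higher over its trend with R80 than with R80A. The windows 1620001 to 1625000, 2230001 to 2235000 and 2290001 to 2295000 (144.8°, 199.3° and 204.6°) had 2.15, 2.64 and 2.12 times the trend with R80 and 1.11, 1.07 and 0.891 with R80A. They were chosen by opt KCK against the median of the libraries, so the 3 other constructs entered the choice through that median. The mean log2 ratio of R80 to R80A over these 3 constructs had a median of 0.32 over the windows. For 95% of random lists it was -0.16 to 0.14, which argues against a background shared by all libraries for that mean only. ECE was the highest of the 3 in each window, with 0.55, 0.87 and 0.52. Untagged Spo0J had 0.04, 0.48 and 0.30, and KCK 0.11, 0.57 and 0.13. Single constructs were not set against random lists. Weak Spo0J-dependent binding far from the origin is a hypothesis that may be followed up with the motif search not analysed here.

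The window 1160001 to 1165000 was at 2.45 times its trend in KCK with R80A and 2.11 in ECE with R80A, against 0.938 to 1.14 in the other 6 libraries. The same 2 libraries were raised in the window 2830001 to 2835000, with 1.9 and 1.75 against 0.997 to 1.22 in the other 6. The window 1985001 to 1990000 was at 2.07 in untagged Spo0J with R80A, against 0.805 to 1.14 in the other 7.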
